A study of Gallus gallus with 12 samples.

How the data were processed

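RNA from 2 leg muscles of female chickens was hybridised to 12 one-colour Agilent arrays, 1 array per sample and 3 per group. The muscles were the soleus and the extensor digitorum longus (EDL). The breeds were the Cobb broiler, sampled at 42 days, and the Qingyuan partridge chicken, sampled at 112 days. Breed and age change together in every sample, so each breed comparison is also a comparison of these ages. Per the labels, both breeds were kept under the same conditions with free access to commercial feed. The labels describe the sampling of the left soleus, on the EDL samples as well, and do not say how the EDL was sampled. They do not say that replicates are separate birds, so p-values measure the spread between these samples, which may be technical in part.

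Per the labels, RNA was extracted with Trizol, amplified from 0.2 µg and labelled with Cy3. The deposited scanner files hold, per the file headers, intensity values made by the authors with Agilent Feature Extraction 10.7.1.1: a processed spot signal after background subtraction, spatial and multiplicative detrending, with low spots set at a surrogate value and no normalization between arrays. The raw mean spot signal and the median local background are also given there as intensity, and the scanner software's quality flags as another unit, yes or no per spot. The deposited value table holds log2 intensity, and the authors' labels do not state how it was made. Checked against the scanner files, its columns matched their own arrays best and shared the same distribution, with a median of 6.98 on each array, as quantile normalization gives.

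The values analysed were log2 of the processed signal minus the array's 75th percentile over non-control spots. Of 43603 non-control probes, 27 were left out because on at least 1 array all of their spots carried an outlier flag. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 38507 of 43576. Genes were named by symbol. Of 13841 probes with a RefSeq accession, 11013 were found in the RefSeq gene table (assembly GRCg7b, used for names and gene neighbours), and 446 probes had their symbol updated through a synonym. A symbol was available for 24739 probes; other probes stay under their accession or clone name. Where several probes share a gene, the brightest was used, which gave 24344 genes or unnamed transcripts tested, 10416 with a symbol. Coordinates are the probe's in the array's annotation, galGal3, and were not checked against names. The array's names differ for ZBTB32 (ZBTB16), CCNB1 (CCNB2), SH2D6 (BLNK), PGK2 (PGK1) and OCM3 (PVALB), whose identity stays open.

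limma 3.58.1 in R 4.3.3 fitted 1 mean per group over the 12 arrays (8 residual degrees of freedom, 2.73 prior degrees of freedom), with trend and robust off. Contrasts were Qingyuan minus Cobb in each muscle, soleus minus EDL in each breed, soleus minus EDL averaged over breeds, and the interaction, which is the soleus minus EDL difference in Qingyuan minus that in Cobb. Genes are called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. All tests are two-sided. Errors after ± are standard errors of the fit. Other tools were the R packages data.table (version 1.17.8) and statmod 1.5.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

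The gene lists were written before the data were examined, as were the comparisons, the main alternative settings and the rule for naming genes. The 23 lists cover slow fibre genes, fast fibre genes, glycolysis, the tricarboxylic acid (TCA) cycle, oxidative phosphorylation, fatty acid oxidation, adipocyte, extracellular matrix, myogenic regulation, fibre type regulators, limb patterning, cell cycle, protein breakdown, ribosomal protein, heat shock, interferon response, erythrocyte, endothelial, leukocyte, nerve, smooth muscle, tendon and cartilage, and W chromosome genes. The W chromosome list had 3 measured members, below the minimum of 5, and was not tested. The other 22 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a contrast. Camera with an estimated correlation and fry were alternatives. Named genes are, in each contrast, the 6 largest rises and 6 largest falls among called genes with a symbol, up to 4 called members of each list by adjusted p, and a fixed panel of muscle genes, of which TNNT1 and COL1A1 are not analysed here. Where a gene was not above background on any array of the lower group, its fold is a lower bound, taken against the lowest level well above background on those arrays or the gene's own value if higher.

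The arrays lie on 3 slides. The first slide holds the 3 Cobb soleus arrays and Cobb EDL replicate 1, the second slide holds Cobb EDL replicates 2 and 3 with Qingyuan soleus replicates 1 and 2, and the third slide holds Qingyuan soleus replicate 3 with the 3 Qingyuan EDL arrays. No slide holds both breeds of the same muscle. A fit with slide as a block was an alternative and its values stand beside key results. For a muscle comparison within a breed it equals the comparison within the only slide that holds both muscles of that breed, an alternative chosen after seeing the data. With the block a breed comparison is reached through the other muscle. In soleus it therefore rests on Cobb EDL replicate 1, and in EDL on Qingyuan soleus replicate 3. The interaction with the block rests on both of these arrays.

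After removal of group means, each soleus sample correlated best across genes with the EDL sample of its own number in its breed (r = 0.219 to 0.468). The labels do not say that the numbers mark birds, so a replicate block was an alternative. For breed it joins equal numbers across breeds, which showed no pairing (r = −0.177 to 0.108). The other alternatives were normexp background correction with quantile normalization, quantile normalization of the processed signal, the values of the deposited table, no filter on dim probes, the mean of a gene's probes, trend and robust on, array weights, only the 2 groups compared, a minimum change of 2-fold, and each array left out in turn. The fit was tested on simulated data with 200 changed genes and no slide effect. Of 67 genes changed by 2 on the log2 scale, it called 44 in breed in soleus, 50 in breed in EDL, 47 in muscle in Cobb and 44 in muscle in Qingyuan. With slide as a block it called 2, 2, 17 and 24 of these. The number of arrays limits the precision.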

Results

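Gene expression was measured in the soleus and the extensor digitorum longus (EDL) of Cobb broilers at 42 days and Qingyuan partridge chickens at 112 days, with 3 arrays in each of the 4 groups. The Cobb broiler is a commercial line bred for fast growth, and the Qingyuan partridge chicken is a slower growing local breed. Each array carried 43803 non-control spots. The share of spots well above background ran from 80.6% on Qingyuan EDL replicate 3 to 93.7% on Qingyuan EDL replicate 1, and 0 spots were saturated. The 75th percentile of the processed signal ran from 506 on Qingyuan EDL replicate 3 to 1402 on Cobb soleus replicate 2. Replicates of a group correlated across genes at r = 0.966 to 0.988, where genes are not independent replicates. The first principal component (29.9% of the variance) placed Cobb EDL replicate 1 at −19.6, against 35.3 and 28.6 for the other two Cobb EDL arrays and −85.8 to −59.1 for Cobb soleus. The second principal component (23.4%) ran from 17.3 to 70.0 in Cobb and from −79.4 to −8.47 in Qingyuan. On Qingyuan EDL replicate 1 the adenovirus E1A control spots had a median signal of 53.2, against 25.5 to 31.8 on the other 11 arrays.

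The first comparison asks which genes differ between the breeds in soleus, where breed and age change together. Cell division and connective tissue genes were lower in Qingyuan soleus. Of 37 measured cell cycle genes, 28 fell and 0 rose (29 and 0 adjusted over the list alone). Their median log2 fold change was −2.11 (camera adjusted p = 2.2e-27; adjusted p = 0.123 with an estimated correlation). KIF20A, a kinesin of cell division (chromosome 13, 10143062 to 10143121), fell by 4.44 ± 0.51, or 21.6-fold (adjusted p = 0.00175). CCNB1, a mitotic cyclin (CCNB2 on the array, chromosome 10, 7788500 to 7788559), BUB1B, a spindle checkpoint kinase, and NUSAP1, a spindle protein, had −2.33 ± 0.22, −1.89 ± 0.22 and −3.24 ± 0.37 (adjusted p = 0.00121, 0.00175 and 0.00175). Of 43 extracellular matrix genes, 22 fell and 0 rose (31 and 1 adjusted over the list alone). Their median was −1.42 (adjusted p = 9.24e-20; adjusted p = 0.137 with an estimated correlation). Beside it, 11 fibroblast identity genes had a median of −1.03, with 3 called lower. COL3A1, a fibrillar collagen (chromosome 7, 566212 to 566271), fell by 2.88 ± 0.37 (adjusted p = 0.00261), and all 10 of its other probes had the same sign. COL5A2, another fibrillar collagen, COL6A2, a chain of collagen VI, and COL4A1, a basement membrane collagen, had −2.43 ± 0.26, −2.16 ± 0.23 and −1.42 ± 0.17 (adjusted p = 0.00138, 0.00138 and 0.00192). The cell cycle median with slide as a block was −2.67 (adjusted p = 2.45e-33) and the matrix median −1.43 (adjusted p = 6.53e-14). KIF20A was then at −5.64 (adjusted p = 0.00127), COL3A1 at −3.68 (adjusted p = 0.0105), and COL4A1 was no longer called (−1.15, adjusted p = 0.104).

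Among the largest falls in soleus, ITGBL1, an integrin beta-like protein (chromosome 1, 147579481 to 147579540), fell by 5.07 ± 0.50 (adjusted p = 0.00121), and SFRP2, a secreted Wnt modulator (chromosome 4, 21143885 to 21143944), fell by 4.70 ± 0.43, or 26.1-fold (adjusted p = 0.0012). Both kept their call with slide as a block (−6.07 and −5.82, adjusted p = 0.0235 and 0.0105). CCN3, a matricellular protein, PXDNL, a peroxidasin-like protein, FNDC1, a fibronectin domain protein, and GATM, an enzyme of creatine synthesis, had −4.95 ± 1.07, −4.81 ± 0.87, −4.55 ± 0.75 and −4.51 ± 1.22 (adjusted p = 0.0223, 0.0108, 0.00701 and 0.0494). None of these 4 was called with slide as a block (−5.76, −5.56, −4.74 and −7.01, adjusted p = 0.247, 0.0832, 0.0968 and 0.178). The CCN3 call ended without Cobb soleus replicate 1 (adjusted p = 0.058) and without Qingyuan soleus replicates 1 or 2 (0.0743 and 0.0829). The GATM call ended without any of the Cobb arrays or Qingyuan soleus replicates 1 or 2 (adjusted p = 0.0518 to 0.161). Of 29 myogenic regulation genes, 6 fell and 0 rose (8 and 0 adjusted over the list alone). The list's median was −0.03 (adjusted p = 0.0122; adjusted p = 0.56 with an estimated correlation), and ran from −0.12 to 0.01 with 1 array left out. IGF1, a growth factor, FST, a myostatin inhibitor, and IGFBP5, an IGF binding protein, had −2.58 ± 0.40, −2.23 ± 0.31 and −1.72 ± 0.23 (adjusted p = 0.00538, 0.00375 and 0.00279). None of these 3 was called with slide as a block (−3.21, −2.64 and −1.48, adjusted p = 0.0954, 0.061 and 0.161). MSTN, which encodes myostatin, was at 0.00 (adjusted p = 0.999). Of 20 tendon and cartilage genes 3 fell, with a median of −1.04 (adjusted p = 0.0016; adjusted p = 0.184 with an estimated correlation). CHAD, a cartilage matrix protein, fell by 2.57 ± 0.42 (adjusted p = 0.00696; −3.31 and adjusted p = 0.0305 with slide as a block). EPYC, a cartilage proteoglycan, was not above background in Qingyuan soleus and at least 2.30-fold lower there (adjusted p = 0.00487; 0.0962 with slide as a block). The myogenic and tendon and cartilage lists were not past the test with slide as a block (adjusted p = 0.127 and 0.0528).

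Fatty acid oxidation genes were higher in Qingyuan soleus. Of 29 measured, 6 rose and 0 fell (10 and 1 adjusted over the list alone). The median was 0.58 (adjusted p = 0.000178; adjusted p = 0.56 with an estimated correlation), and 1.40 with slide as a block (adjusted p = 1.71e-14). CD36, a fatty acid transporter, and PPARGC1B, a transcriptional coactivator, rose by 1.28 ± 0.26 and 1.20 ± 0.24 (adjusted p = 0.0175 and 0.0153). PDK4, an inhibitor of pyruvate dehydrogenase, rose by 3.14 ± 0.81 (adjusted p = 0.042; 6.56 and adjusted p = 0.019 with slide as a block). Neither CD36 nor PPARGC1B was called with slide as a block (1.78 and 0.98, adjusted p = 0.13 and 0.348). The CD36 call ended without Cobb soleus replicates 2 or 3 or Qingyuan soleus replicate 2 (adjusted p = 0.0771, 0.0584 and 0.0638). The PPARGC1B call ended without Cobb soleus replicates 1 or 2 or Qingyuan soleus replicate 1 (0.0651, 0.0635 and 0.0666), and the PDK4 call ended without any of the 6 soleus arrays or Qingyuan EDL replicate 3 (0.0534 to 0.138) and with a replicate block (adjusted p = 0.0534). Of 29 adipocyte genes, 1 rose and 4 fell. Their median was −0.62 (adjusted p = 0.00621; adjusted p = 0.56 with an estimated correlation) and turned to 0.43 with slide as a block (adjusted p = 0.541). FADS1, a fatty acid desaturase, fell by 1.59 ± 0.26 (adjusted p = 0.00611; −2.50 and adjusted p = 0.012 with slide as a block). FADS2, of the same family, fell by 1.78 ± 0.31 (adjusted p = 0.00861; −1.82 and adjusted p = 0.195 with slide as a block). Of 17 erythrocyte genes 2 rose (10 up and 1 down adjusted over the list alone). Their median was 0.88 (adjusted p = 0.000741; adjusted p = 0.56 with an estimated correlation), and 1.73 with slide as a block (adjusted p = 8.71e-07). KLF1, an erythroid transcription factor, rose by 1.62 ± 0.30 (adjusted p = 0.012). The KLF1 call ended without Cobb soleus replicate 3 (adjusted p = 0.0502) or Qingyuan soleus replicate 1 (0.0537), and with slide as a block (2.35, adjusted p = 0.0659).

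Other lists also passed the test. Ribosomal protein genes had a median of 0.39 (adjusted p = 7.25e-08), oxidative phosphorylation 0.40 (6.87e-06), protein breakdown 0.43 (0.00553) and the TCA cycle 0.29 (0.0337). Of their members 2 of 62, 0 of 58, 3 of 38 and 0 of 18 were called higher. With an estimated correlation their adjusted p = 0.56, 0.636, 0.56 and 0.752, and none of these 4 passed with normexp or quantile normalization (medians 0.01 to 0.24, adjusted p = 0.0745 to 0.898). Glycolysis had a median of −0.34 with 1 of 28 called lower (adjusted p = 0.0342; adjusted p = 0.636 with an estimated correlation), and its call ended without Cobb soleus replicates 1 or 3 (0.082 and 0.227) or Qingyuan soleus replicate 3 (0.39) and with array weights (0.0709). Its median ran from −0.45 to −0.14 with 1 array left out, and was −0.59 under quantile normalization. The ribosomal protein, protein breakdown and glycolysis lists were not past the test with slide as a block (adjusted p = 0.326, 0.0882 and 0.251). The TCA cycle median was then 0.85 (adjusted p = 2.57e-06). Its call ended without Cobb soleus replicates 2 or 3 (0.0963 and 0.112), Qingyuan soleus replicate 1 (0.0538) or Qingyuan EDL replicate 1 (0.0504). Not past the test were slow fibre genes (median 0.55, adjusted p = 0.682), fast fibre genes (0.18, 0.839), fibre type regulators (0.17, 0.805), limb patterning (0.22, 0.805), heat shock (0.06, 0.965) and interferon response genes (0.27, 0.081). The fast fibre mean was −0.15. That list turned and passed as lower with normexp (−0.29, adjusted p = 0.00939), quantile normalization (−0.24, 0.0162) and the deposited table (−0.24, 0.0163). Markers of other cell types not past the test were endothelial (0.05, 0.519), leukocyte (0.23, 0.965), nerve (−0.16, 0.497) and smooth muscle genes (−0.09, 0.506). Of the lists not past the test, 4 passed with slide as a block: slow fibre (2.38, adjusted p = 9.79e-06), heat shock (1.20, 2.27e-05), interferon response (0.39, 0.0126) and endothelial genes (0.46, 0.0201). Without the block and with an estimated correlation these 4 had adjusted p = 0.987, 0.987, 0.636 and 0.937. The block values for breed in soleus rest on Cobb EDL replicate 1, the array that lay nearer to soleus. The slow fibre median of soleus minus EDL in Cobb went from 3.50 to 1.70 with the block. The slow myosin gene MYH7 was at 0.55 (adjusted p = 0.483), TNNI1, slow troponin I, at 0.59 (0.772), MYLPF, a fast myosin light chain, at −0.07 (0.947) and PVALB, the calcium buffer parvalbumin, at −3.91 ± 1.65 (0.17). Beside PDK4, the largest rise was that of IQUB at 3.17 ± 0.42 (adjusted p = 0.00281; 3.18 and adjusted p = 0.12 with slide as a block). The zinc finger gene ZBTB32 was at 3.11 ± 0.67, the ion channel gene CNGA1 at 3.05 ± 0.56, the egg coat gene ZP1 at 3.03 ± 0.62 and FAM26F at 2.92 ± 0.74 (adjusted p = 0.0216, 0.0119, 0.0172 and 0.0388). Blocked by slide, none of these 4 was called (5.26, 1.67, 3.50 and 2.45, adjusted p = 0.0566, 0.435, 0.232 and 0.471). Left-out arrays ended the calls of ZBTB32 (Cobb soleus replicates 2 and 3, Qingyuan soleus replicates 1 and 2; adjusted p = 0.0602 to 0.0881), CNGA1 (Cobb soleus replicate 2; 0.0521), ZP1 (the 3 Cobb soleus arrays and Qingyuan soleus replicate 2; 0.0563 to 0.0648) and FAM26F (Cobb soleus replicates 1 and 3, Cobb EDL replicates 2 and 3, the 3 Qingyuan soleus arrays and Qingyuan EDL replicate 3; 0.0505 to 0.136). A replicate block also ended the FAM26F call (adjusted p = 0.0676).

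In soleus 1802 of 24344 genes were called, 709 higher and 1093 lower in Qingyuan. The median log2 fold change of all genes was 0.13. A fit with slide as a block called 331 genes (126 higher), of which 208 were among the 1802, and 13 of the 55 named genes called. With a replicate block 1563 genes were called, 1401 of them among the 1802. With normexp the cell cycle median was −1.37 and that of tendon and cartilage genes −0.62, and KIF20A, NUSAP1, ITGBL1, IGF1 and CNGA1, still called, were at −2.80, −1.87, −3.35, −0.78 and 1.97. CCN3, PDK4, GATM and FAM26F were then not called (adjusted p = 0.068, 0.0675, 0.06 and 0.098). Without the filter PDK4, GATM and FAM26F were not called (0.0569, 0.0662 and 0.0531), and under quantile normalization PDK4 and FAM26F (0.0529 and 0.0519). With the mean of a gene's probes GATM was not called (0.0613), and IQUB, PXDNL and BUB1B were at 1.27, −2.44 and −2.90. The count was 640, 576 and 708 without Cobb soleus replicates 1, 2 and 3, and 614 and 689 without Qingyuan soleus replicates 1 and 2, and stayed between 1350 and 2546 without any of the others.

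The second comparison asks the same question in EDL. Cell cycle genes were lower in Qingyuan EDL as well, with 24 of 37 called lower and 0 higher (30 and 1 adjusted over the list alone). Their median was −1.80 (adjusted p = 1.23e-20; adjusted p = 0.256 with an estimated correlation). KIF20A fell by 3.48 ± 0.51, or 11.2-fold, CCNB1 by 2.37 ± 0.22, BUB1B by 2.08 ± 0.22 and NUSAP1 by 2.91 ± 0.37 (adjusted p = 0.00796, 0.00169, 0.00241 and 0.00534). MCM3, a replication factor, fell by 2.15 ± 0.29 (adjusted p = 0.0057; −2.72 and adjusted p = 0.0749 with slide as a block). Of 43 extracellular matrix genes 6 fell and 0 rose (16 and 0 adjusted over the list alone). Their median was −0.78 (adjusted p = 2.35e-08; adjusted p = 0.426 with an estimated correlation), beside −0.32 for the 11 fibroblast identity genes, with 0 called. COL6A2 fell by 1.68 ± 0.23 (adjusted p = 0.00651; −2.41 and adjusted p = 0.0333 with slide as a block), and COL3A1 was at −1.28 (adjusted p = 0.0668). Blocked by slide, the medians were −2.77 for the cell cycle (adjusted p = 1.7e-33) and −1.27 for the matrix (adjusted p = 2.72e-15), and KIF20A was at −5.94 (adjusted p = 0.00165). IGFBP5 fell by 1.74 ± 0.23 (adjusted p = 0.0056; −1.60 and adjusted p = 0.166 with slide as a block). The myogenic regulation list, with 1 of 29 called lower, had a median of −0.37 (adjusted p = 0.0368; adjusted p = 0.426 with an estimated correlation). That list's call ended without Cobb EDL replicate 1 (−0.16, adjusted p = 0.0848), without Qingyuan EDL replicates 2 or 3 (−0.27 and −0.21, adjusted p = 0.0513 and 0.0659) and with slide as a block (−0.12, adjusted p = 0.0795).

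The largest rise was that of ZBTB32 (chromosome 24, 4504283 to 4504342) at 5.91 ± 0.67, or 60.1-fold (adjusted p = 0.0029; 7.73 and adjusted p = 0.0272 with slide as a block). ZP1 rose by 3.71 ± 0.62, the coiled-coil gene CCDC69 by 3.44 ± 0.48 and the annexin gene ANXA13 by 3.28 ± 0.77 (adjusted p = 0.0112, 0.00671 and 0.0347). FGF6, a fibroblast growth factor of muscle, rose by 3.15 ± 0.42 and FGF23, a hormone of phosphate balance, by 2.93 ± 0.25 (adjusted p = 0.00568 and 0.00169). None of these 5 was called with slide as a block (3.78, 2.29, 3.60, 2.88 and 2.62, adjusted p = 0.231, 0.26, 0.338, 0.133 and 0.0622). The ANXA13 call also ended without Cobb soleus replicates 2 or 3, Cobb EDL replicates 1 or 3, Qingyuan soleus replicate 1 or Qingyuan EDL replicate 2 (adjusted p = 0.05 to 0.114). Beside KIF20A, the largest falls were those of the collagen gene COL20A1 at −4.54 ± 0.77, PENK, an opioid peptide precursor, at −4.38 ± 0.81 and FHL2, a LIM domain protein, at −3.92 ± 1.01 (adjusted p = 0.0115, 0.0155 and 0.0471). NELL2, a secreted glycoprotein, was at −3.86 ± 0.43 and FNDC1 at −3.74 ± 0.75 (adjusted p = 0.00285 and 0.0212). NELL2 was also called with slide as a block (−5.26, adjusted p = 0.0174). COL20A1, PENK, FHL2 and FNDC1 were not (−5.86, −7.15, −1.95 and −5.95, adjusted p = 0.128, 0.059, 0.444 and 0.0746). Without Cobb EDL replicates 2 or 3 or Qingyuan EDL replicate 3 PENK was not called (adjusted p = 0.0509, 0.0623 and 0.0501). FNDC1 was not called without any of the 3 Cobb EDL arrays or Qingyuan EDL replicate 3 (adjusted p = 0.0572 to 0.0652). The FHL2 call ended without any 1 array other than Cobb EDL replicate 2 or Qingyuan EDL replicate 1 (adjusted p = 0.0534 to 0.134).

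Oxidative pathway lists were higher in Qingyuan EDL. Oxidative phosphorylation had 3 of 58 members called higher (14 adjusted over the list alone), fatty acid oxidation 3 of 29 (6 adjusted over the list alone) and the TCA cycle 0 of 18. The medians were 0.43, 0.42 and 0.49 (adjusted p = 2.09e-08, 0.000362 and 0.000127), each with adjusted p = 0.426 with an estimated correlation. Their medians with slide as a block were 0.60, 0.87 and 0.80 (adjusted p = 4.6e-07, 4.6e-07 and 7.02e-06). The TCA cycle call ended with normexp and quantile normalization (adjusted p = 0.133 and 0.054), where the oxidative phosphorylation medians were 0.16 and 0.20. The fatty acid oxidation median was 0.27 with normexp. Array weights gave medians of 0.70 for fatty acid oxidation and 0.76 for the TCA cycle, and the fatty acid oxidation median was 0.71 without Cobb EDL replicate 1. Erythrocyte genes had a median of 1.07 with 3 higher and 1 lower of 17 (adjusted p = 0.00148; adjusted p = 0.426 with an estimated correlation). SLC4A1, the red cell anion exchanger, was at 1.19 ± 0.20 and HBA1, an alpha globin, at 1.45 ± 0.29 (adjusted p = 0.0112 and 0.0198). Neither was called with slide as a block (1.31 and 2.35, adjusted p = 0.17 and 0.0502). Without Cobb EDL replicate 3 neither was called (adjusted p = 0.0531 and 0.0788), and HBA1 also not without Cobb EDL replicate 2 (0.0583) or Qingyuan EDL replicates 2 or 3 (0.0504 and 0.0544). Ribosomal protein (median 0.38, adjusted p = 1.03e-08), protein breakdown (0.37, 0.00122) and tendon and cartilage genes (−0.51, 0.0368) also passed, each with adjusted p = 0.426 with an estimated correlation. None of these 3 passed under quantile normalization (adjusted p = 0.0697, 0.0536 and 0.0536). Ribosomal protein and tendon and cartilage genes did not pass with normexp (0.105 and 0.0649), nor the latter without the filter (0.0914) or with array weights (0.0506), and with slide as a block the ribosomal protein list did not pass (adjusted p = 0.135) while protein breakdown was at 0.58 (0.00184). The ribosomal protein median was 0.25 without Qingyuan EDL replicate 3, and the tendon and cartilage median −0.29 without Qingyuan EDL replicate 2. The protein breakdown call ended without Qingyuan EDL replicate 2 (0.0826), and the tendon and cartilage call without Cobb EDL replicate 1 or Qingyuan EDL replicates 1 or 3 (0.0626, 0.0751 and 0.0748). TAP2, the peptide transporter of antigen presentation, rose by 1.73 ± 0.29 (adjusted p = 0.0112; 0.97 and adjusted p = 0.381 with slide as a block). Slow fibre genes (median −0.03, adjusted p = 0.728), fast fibre genes (0.20, 0.185), glycolysis (−0.22, 0.124) and adipocyte genes (−0.14, 0.21) did not pass. Glycolysis passed as lower under quantile normalization (−0.36, adjusted p = 0.0172; adjusted p = 0.0206 with normexp). Blocked by slide, the fast fibre list passed (0.56, adjusted p = 0.0263), as did leukocyte genes (−0.38, adjusted p = 0.0241; −0.22 and 0.128 without the block). Without the block and with an estimated correlation their adjusted p = 0.891 and 0.779. In EDL 1438 genes were called, 728 higher and 710 lower. A fit with slide as a block called 130 genes (22 higher), 104 of them shared, and 9 of the 50 named genes called. With the replicate block across breeds 1248 genes were called, 1084 of them shared. A fit of only the 2 groups compared called 146 genes (31 higher), 134 of them shared. With normexp the cell cycle median was −1.09 and the erythrocyte median 0.56, and KIF20A, NUSAP1, BUB1B, FGF6 and FGF23, still called, were at −2.30, −1.68, −1.35, 2.09 and 1.34. ANXA13 and FHL2 were then not called (0.84 and −2.51, adjusted p = 0.115 and 0.0914). The FHL2 call also ended without the filter (0.0635) and with the mean of a gene's probes (0.0521), as did that of SLC4A1 with this mean (0.0696), where TAP2 was at 1.12 and the erythrocyte median 0.55. The count was 803, 784 and 825 without Cobb soleus replicates 1, 2 and 3, 873, 585 and 311 without Cobb EDL replicates 1, 2 and 3, 2431, 852 and 618 without Qingyuan EDL replicates 1, 2 and 3, and 1092 to 1783 without the rest.

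**Figure D1:**
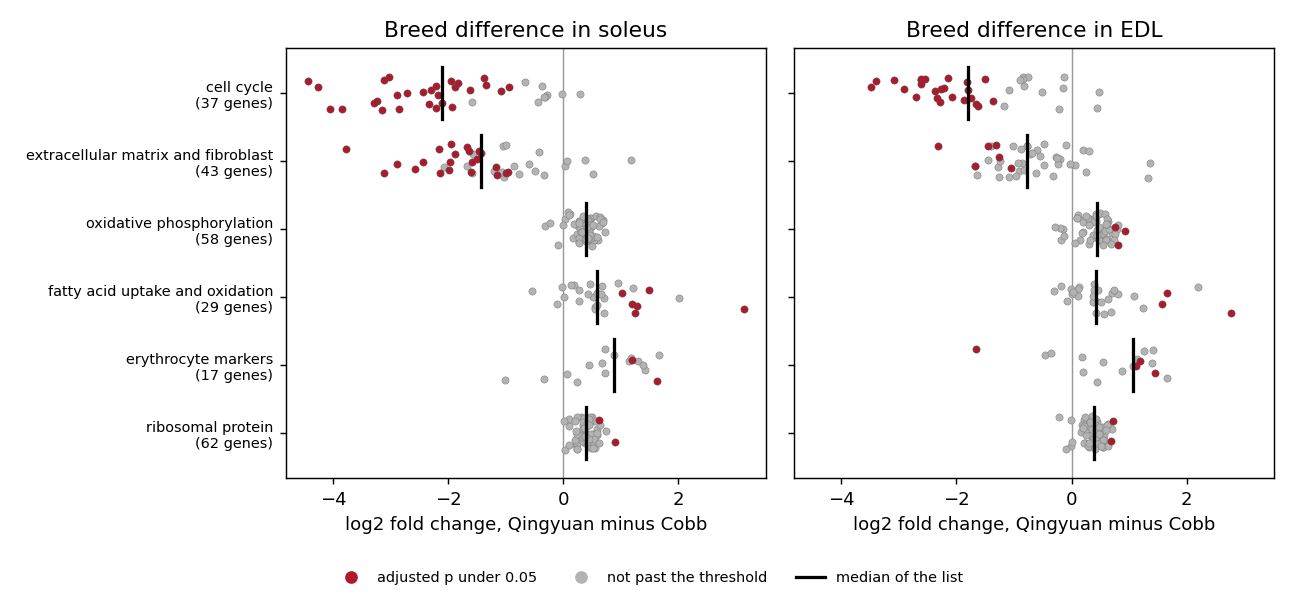
Log2 fold change, Qingyuan minus Cobb, of each measured member of the named gene lists (points) with the list's median (bar), in soleus and in EDL. The cell cycle medians are −2.11 and −1.80 and the extracellular matrix medians −1.42 and −0.78.

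Breed differences were compared between the muscles. Of the genes called higher in Qingyuan, 265 were called in both muscles, against 21.2 for independent calls, and of those called lower 454, against 31.9. Samples of the same number deviate together in the muscles of a breed (r = 0.219 to 0.468), so the comparisons share variation between samples, and neither the counts for independent calls nor r = 0 is the value without a breed difference. In each direction 1 gene was called with opposite signs. KIF20A, CCNB1, BUB1B, NUSAP1 and COL6A2 were among those lower in both. ZBTB32 was among those higher in both, its soleus call ending without any of the 4 arrays named for it. Across the 24344 genes the log2 fold changes of the muscles correlated at r = 0.628, with no p because genes are not replicates. Of genes called in either muscle, 94.7% had the same sign in both.

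The third comparison asks which genes separate soleus from EDL in Cobb. Slow fibre genes were higher in Cobb soleus, with 8 of 20 called higher and 0 lower (14 and 1 adjusted over the list alone). Their median was 3.50 (adjusted p = 2.45e-15; adjusted p = 0.209 with an estimated correlation). MYH7, a slow myosin heavy chain, was higher by 5.54 ± 0.46, or 46.6-fold, and ATP2A2, the slow muscle calcium pump, by 5.65 ± 0.47, or 50.3-fold (adjusted p = 0.000723 for both). The only slide with both Cobb muscles holds 3 soleus arrays and 1 EDL array, Cobb EDL replicate 1, the array that lay nearer to soleus, so within-slide values in Cobb rest on that 1 array. Within the slide they were at 5.39 and 5.24 (adjusted p = 0.0334 and 0.035), and the list's median was 1.70 (adjusted p = 8.65e-07). TNNI1 was higher by 8.59 ± 1.08 and TNNC1, slow troponin C, by 6.42 ± 0.76 (adjusted p = 0.00689 and 0.00424). TNNI3K, a kinase that binds cardiac troponin I, was higher by 6.86 ± 0.79 and PROX1, a homeobox transcription factor, by 4.11 ± 0.53 (adjusted p = 0.00375 and 0.00711). Within the slide these 4 were at 7.02, 5.79, 6.32 and 3.26 and not called (adjusted p = 0.128, 0.104, 0.0937 and 0.113). MYH7B, another slow myosin heavy chain, was at 9.76 ± 1.32 and MYL2, a slow myosin light chain, at 7.29 ± 1.03 (adjusted p = 0.0095 and 0.0109). The MYH7B call ended without Cobb soleus replicates 1 or 2 (0.0577 and 0.0608) and within the slide (7.18, adjusted p = 0.149). That of MYL2 ended without the same arrays (0.0578 and 0.0529) and without Cobb EDL replicates 2 or 3 (0.0577 and 0.0507), and within the slide (6.16, adjusted p = 0.162).

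Fatty acid oxidation genes were also higher in Cobb soleus, with a median of 0.97 and 2 of 29 called higher (19 and 1 lower adjusted over the list alone; adjusted p = 3.77e-12; adjusted p = 0.31 with an estimated correlation). FABP3, a fatty acid binding protein of muscle, was higher by 1.72 ± 0.26 (adjusted p = 0.0159). TCA cycle genes (median 0.52, adjusted p = 1.53e-08) and oxidative phosphorylation genes (0.28, 1.03e-08) were higher as lists, with adjusted p = 0.372 and 0.548 with an estimated correlation, and 0.27 and 0.17 within the slide (adjusted p = 0.00796 and 0.00267). Fast fibre genes had a median of −0.76 and glycolysis −0.85 (adjusted p = 3.53e-07 and 4.02e-05; adjusted p = 0.481 and 0.372 with an estimated correlation). Of their members 0 of 18 and 1 of 28 were called lower (8 and 15 adjusted over the list alone). Within the slide the medians were 0.42 for fatty acid oxidation, −0.48 for fast fibre genes and −0.57 for glycolysis (adjusted p = 0.00168, 0.0036 and 0.000159). OCM3, of the parvalbumin family, was at −2.77 ± 0.44 and EMX2, a homeobox transcription factor, at −4.21 ± 0.76 (adjusted p = 0.0189 and 0.0321). PVALB was at −5.29 (adjusted p = 0.123) and LDHA, a lactate dehydrogenase of fast muscle, at −1.36 (adjusted p = 0.189). Also among the largest differences were MYL10, a myosin light chain, at 8.42 and SPTSSB, a subunit of serine palmitoyltransferase, at least 48.7-fold higher (adjusted p = 0.0362 and 0.0241). NEUROD6, a transcription factor, was at −3.47, TNFRSF11B, or osteoprotegerin, at −2.09, MMP7, a metalloproteinase, at −2.04 and AvBD9, a defensin, at −1.92 (adjusted p = 0.035, 0.0321, 0.0486 and 0.0407). These 6 genes, OCM3, EMX2 and FABP3 each lost the call within the slide and without Cobb EDL replicate 3 or any of the 3 Cobb soleus arrays (adjusted p = 0.0511 to 0.194). All but TNFRSF11B also lost it without Cobb EDL replicate 2 (adjusted p = 0.051 to 0.15), and MYL10, NEUROD6, TNFRSF11B, MMP7 and AvBD9 without Qingyuan soleus replicate 1 (0.0503 to 0.0746). MYL10, MMP7 and AvBD9 also lost it without Qingyuan soleus replicate 3 (0.0539, 0.0597 and 0.0514), MMP7 and AvBD9 without Qingyuan EDL replicate 3 (0.0592 and 0.0522), and MMP7 without Qingyuan soleus replicate 2 (0.0605). A replicate block ended the calls of MYL10, SPTSSB, NEUROD6, MMP7 and AvBD9 (adjusted p = 0.0542, 0.0555, 0.0567, 0.0516 and 0.0837).

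Endothelial genes had a median of 0.39 with 3 of 21 called higher (adjusted p = 0.000108; adjusted p = 0.372 with an estimated correlation), and −0.03 within the slide (adjusted p = 0.459). The median was 0.77 without Cobb EDL replicate 1 and 0.25 without Cobb EDL replicates 2 or 3. Heat shock genes were at −0.17 (adjusted p = 0.814). Their median was −0.77 within the slide, which rests on Cobb EDL replicate 1, and 0.20 without that array, past the test the other way (adjusted p = 0.041). Tendon and cartilage genes had a median of 0.70 (adjusted p = 0.000577; adjusted p = 0.209 with an estimated correlation) and 0.59 within the slide (adjusted p = 0.0139). Cell cycle genes had 0.36, adipocyte genes 0.34, extracellular matrix genes 0.10 and ribosomal protein genes −0.23 (adjusted p = 0.00137, 0.0079, 0.021 and 0.00171; adjusted p = 0.612, 0.548, 0.686 and 0.686 with an estimated correlation). The last 3 of these were not past the test within the slide (adjusted p = 0.886, 0.304 and 0.717), and the cell cycle median was 0.64 there (adjusted p = 1.82e-08). Left-out arrays ended the calls of the cell cycle (Cobb EDL replicate 1; 0.0637), adipocyte (Cobb EDL replicate 2; 0.0813) and matrix lists (Cobb soleus replicate 3 and Cobb EDL replicate 2; 0.17 and 0.0505). The matrix median ran from 0.05 to 0.15 with 1 array left out and was 0.28 under quantile normalization, and its call ended with the mean of a gene's probes (0.0572). The ribosomal protein call ended with normexp and quantile normalization (0.0973 and 0.279), where the fast fibre medians were −0.34 and −0.32. In Cobb 290 genes were called, 212 higher in soleus and 78 lower. Within the slide 75 genes were called (24 higher), 16 of them among the 290, and 3 of the 28 named genes called. With a replicate block 214 genes were called, 147 of them among the 290. With normexp MMP7 was not called (adjusted p = 0.0516) and TNNI3K, EMX2 and NEUROD6, still called, were at 3.33, −2.23 and −1.30. Without the filter MYL10, NEUROD6, MMP7 and AvBD9 were not called (0.0533, 0.0507, 0.0694 and 0.0589). Without Cobb EDL replicate 1, which lay nearer to soleus in the principal components, 1640 genes were called (713 higher, 43.5%). The count was 41, 34 and 117 without Cobb soleus replicates 1, 2 and 3, and 46 and 51 without Cobb EDL replicates 2 and 3. It was 182 without Qingyuan soleus replicate 1, 460 and 440 without Qingyuan EDL replicates 1 and 2, and 226 to 276 without the rest.

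The same comparison was made in Qingyuan, where slow fibre genes were again higher in soleus. Of 20 slow fibre genes 12 were higher in soleus and 0 lower (16 and 1 adjusted over the list alone). Their median was 4.98 (adjusted p = 8.84e-14; adjusted p = 0.517 with an estimated correlation). MYH7B (chromosome 20, 2585556 to 2585615) was higher by 10.38 ± 1.32 and TNNI1 (chromosome 26, 772092 to 772151) by 9.10 ± 1.08 (adjusted p = 0.00267 and 0.00183). ATP2A2 (chromosome 15, 5347355 to 5347414) was higher by 7.39 ± 0.47, or 167-fold, and MYH7 (chromosome 19, 13469 to 13527) by 6.09 ± 0.46, or 67.9-fold (adjusted p = 4.74e-05 and 0.000193). TNNC1 was at 8.56 ± 0.76, MYL2 at 7.35 ± 1.03 and PROX1 (chromosome 3, 22432218 to 22432277) at 5.47 ± 0.53 (adjusted p = 0.000389, 0.00425 and 0.000497). The only slide with both Qingyuan muscles holds 3 EDL arrays and 1 soleus array, Qingyuan soleus replicate 3, so within-slide values in Qingyuan rest on that 1 array. Within the slide these 7 genes were called (MYH7B at 10.56, adjusted p = 0.0289; ATP2A2 at 7.48, adjusted p = 0.00796), and the list's median was 4.99 (adjusted p = 2.01e-15). TECRL, a reductase-like protein of heart muscle, was higher by 9.55 ± 0.92 and MYL10 by 8.53 ± 1.59 (adjusted p = 5e-04 and 0.0148). The MYL10 call ended without Qingyuan soleus replicate 1 (0.0593) and within the slide (adjusted p = 0.066).

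Fatty acid oxidation genes were higher in Qingyuan soleus, with 13 of 29 called higher and 0 lower (18 and 0 adjusted over the list alone). Their median was 0.99 (adjusted p = 2.63e-10; adjusted p = 0.606 with an estimated correlation) and 0.97 within the slide (adjusted p = 4.8e-10). CD36 (chromosome 1, 12076132 to 12076191) was higher by 1.96 ± 0.26, or 3.89-fold, PPARA, a nuclear receptor of lipid metabolism, by 1.93 ± 0.24 and FABP3 by 1.88 ± 0.26 (adjusted p = 0.00346, 0.00218 and 0.00402). All 3 were called within the slide (1.74, 1.86 and 1.83; adjusted p = 0.049, 0.0315 and 0.0399). Fast fibre genes had 4 of 18 called lower (14 adjusted over the list alone), and glycolysis 10 lower and 1 higher of 28 (14 and 1 adjusted over the list alone). Their medians were −0.88 and −0.73 (adjusted p = 1.81e-07 and 0.000171; adjusted p = 0.606 with an estimated correlation for both), and both lists passed within the slide (adjusted p = 3.54e-08 and 1.45e-05). PVALB was at −9.17 ± 1.65, MYBPC2, a fast myosin binding protein, at −4.54 ± 0.90, PHKB, a subunit of phosphorylase kinase, at −1.93 ± 0.33 and LDHA at −2.57 ± 0.52 (adjusted p = 0.013, 0.0178, 0.0104 and 0.0197). These 4 calls ended without Qingyuan soleus replicate 1 (0.0553, 0.0758, 0.0504 and 0.0814). The MYBPC2 and LDHA calls also ended without Qingyuan EDL replicate 3 (0.0584 and 0.0689), and the LDHA call with a replicate block (adjusted p = 0.0535) and within the slide (adjusted p = 0.0902). Within the slide PVALB was at −11.77 and MYBPC2 at −6.32 (adjusted p = 0.026 and 0.0332). The other largest falls were MAFA, a transcription factor, at −4.97 ± 0.86, KCNG1, a potassium channel subunit, at −4.98, GATM at −4.64 and GPM6A, a membrane glycoprotein that was at least 24.8-fold lower (adjusted p = 0.0107, 0.0499, 0.0476 and 0.0316). The MAFA call ended without Qingyuan soleus replicate 1 (0.0518), and none of these 3 other genes was called within the slide. The KCNG1 call ended without any 1 array other than Cobb soleus replicates 1 or 3 or Cobb EDL replicate 1 (adjusted p = 0.0504 to 0.129). The GATM call ended without any other than Cobb EDL replicate 1, Qingyuan soleus replicate 3 or Qingyuan EDL replicate 2 (0.0552 to 0.142), and the GPM6A call without Cobb soleus replicates 1 or 3, Qingyuan EDL replicates 1 or 3 or any Qingyuan soleus array (0.0507 to 0.0949).

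TCA cycle and oxidative phosphorylation genes had medians of 0.35 and 0.27 (adjusted p = 0.000487 and 4.71e-05), and endothelial genes 0.38 with 3 of 21 called higher (adjusted p = 0.000595), all with adjusted p = 0.606 with an estimated correlation. Without Qingyuan EDL replicate 2 the first 2 medians were 0.22 and 0.12, that of oxidative phosphorylation was 0.44 without Qingyuan EDL replicate 3, and the endothelial median was 0.61 without Qingyuan soleus replicate 3. CDH19, a cadherin of Schwann cells, was higher by 2.49 ± 0.33 (adjusted p = 0.00337; 3.02 and adjusted p = 0.0202 within the slide). Interferon response genes (0.55, 0.0304), leukocyte genes (0.49, 0.0102), extracellular matrix genes (−0.37, 0.0102) and ribosomal protein genes (−0.23, 0.0027) also passed, with adjusted p = 0.606, 0.606, 0.606 and 0.698 with an estimated correlation. The interferon response call ended without Qingyuan soleus replicate 3 or Qingyuan EDL replicates 1 or 3 (0.235, 0.27 and 0.0574), and the leukocyte call without the same arrays or Qingyuan soleus replicate 2 (0.11, 0.0938, 0.0692 and 0.112). With 1 array left out the leukocyte median ran from 0.24 to 0.75 and the matrix median from −0.59 to −0.15. The matrix call ended without Qingyuan soleus replicate 2 or Qingyuan EDL replicate 2 (0.267 and 0.0928), and the ribosomal protein call without Qingyuan soleus replicate 2 or Qingyuan EDL replicate 3 (0.112 and 0.406). Neither of these lists passed within the slide (adjusted p = 0.422 and 0.311), where the endothelial median was 0.16 and the leukocyte median 0.89 (adjusted p = 0.00408 and 0.00026). Cell cycle genes were at −0.02 (adjusted p = 0.955). Their median was 0.69 within the slide, which rests on Qingyuan soleus replicate 3, and −0.34 without that array, past the test the other way (adjusted p = 0.00703). COL3A1 was at −1.95 ± 0.37 (adjusted p = 0.0161), and its call ended without Qingyuan soleus replicate 1 (0.066) and within the slide (−0.97, adjusted p = 0.145). In Qingyuan 1635 genes were called, 799 higher in soleus and 836 lower. Within the slide 656 genes were called, 474 of them shared, and 23 of the 50 named genes called. With a replicate block 1668 genes were called, 1157 of them shared. GATM, GPM6A and KCNG1 were not called with normexp (adjusted p = 0.0641, 0.145 and 0.0866). GATM and KCNG1 were also not called without the filter (0.0644 and 0.067) or with the mean of a gene's probes (0.0617 and 0.0817), nor KCNG1 with array weights (0.218). The interferon response and leukocyte calls ended with array weights (0.158 and 0.108). The count was 962, 1038 and 1033 without Cobb soleus replicates 1, 2 and 3, 389 without Qingyuan soleus replicate 1, 642 without Qingyuan EDL replicate 3 and 1097 to 2172 without the rest.

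**Figure D2:**
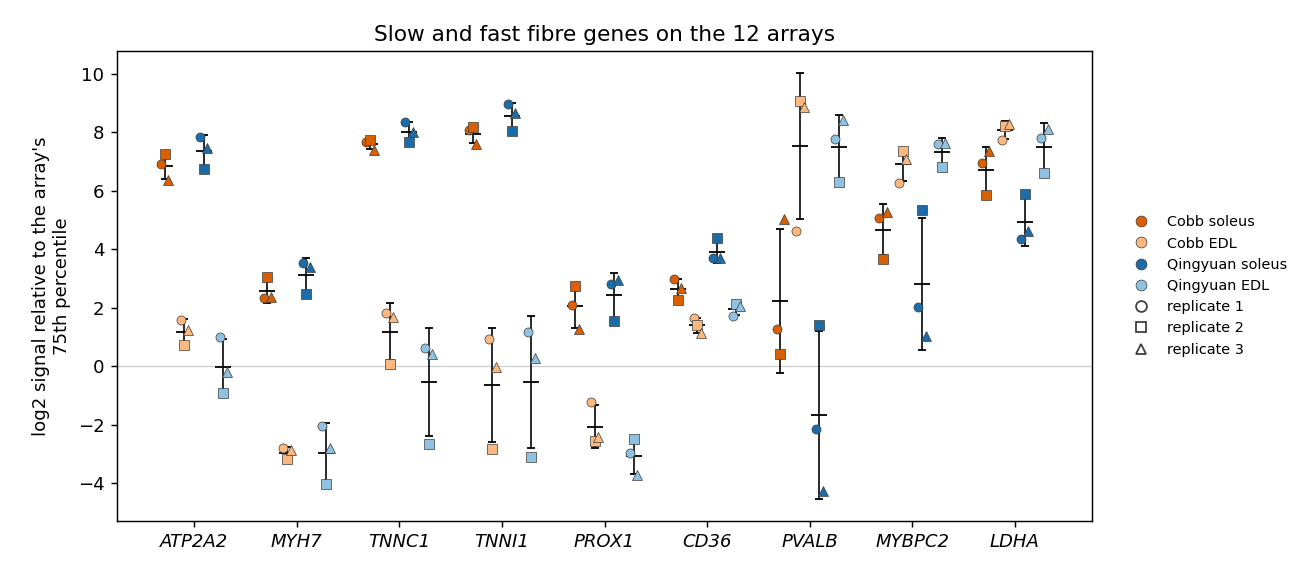
Scaled log2 signal of slow and fast muscle genes on each of the 12 arrays (points) with the mean of each group and its SD (bars, n = 3). MYH7 and ATP2A2 lie higher in soleus than in EDL in both breeds.

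Muscle differences were compared between the breeds. Of the genes called higher in soleus 142 were called in both breeds, against 6.96 for independent calls, and of those called lower 45, against 2.68, with 0 called in opposite directions. MYH7, TNNI1, TNNC1, ATP2A2 and PROX1 were among the genes higher in soleus in both. Across genes the log2 fold changes correlated at r = 0.648, and 94.3% of genes called in either breed had the same sign. Averaged over the breeds, slow fibre genes had a median of 4.02 with 16 of 20 higher and 1 lower (adjusted p = 8.35e-15; adjusted p = 0.323 with an estimated correlation). Fatty acid oxidation genes had 1.04 with 21 of 29 higher and 1 lower (adjusted p = 2.11e-12; adjusted p = 0.323 with an estimated correlation), and 0.65 with slide as a block (adjusted p = 1.05e-08). Fast fibre genes had a median of −0.84 with 14 of 18 lower and glycolysis −0.71 with 14 of 28 lower and 1 higher (adjusted p = 2.34e-08 and 3.67e-05; adjusted p = 0.43 and 0.429 with an estimated correlation). TCA cycle genes had 0.44 with 8 of 18 higher and oxidative phosphorylation 0.27 with 11 of 58 higher (adjusted p = 4.7e-07 and 2.85e-08; adjusted p = 0.43 and 0.601 with an estimated correlation). Markers of other cell types also passed: endothelial genes at 0.36 with 7 of 21 higher, tendon and cartilage genes at 0.58 with 4 of 20 higher and leukocyte genes at 0.35 with 6 higher and 3 lower of 37 (adjusted p = 7.01e-05, 0.00618 and 0.0295; adjusted p = 0.411, 0.323 and 0.65 with an estimated correlation). Adipocyte genes were at 0.34 with 3 higher and 2 lower of 29 and ribosomal protein genes at −0.24 with 1 higher and 2 lower of 62 (adjusted p = 0.0422 and 0.0004; adjusted p = 0.645 and 0.65 with an estimated correlation). Leukocyte, adipocyte and ribosomal protein genes did not pass with slide as a block (0.36, 0.03 and −0.12, adjusted p = 0.125, 0.657 and 0.369), where the TCA cycle and endothelial medians were 0.27 and 0.14. Under quantile normalization leukocyte and adipocyte genes did not pass (0.0622 and 0.0913), and the fast fibre and ribosomal protein medians were −0.54 and −0.11. With normexp adipocyte genes did not pass (0.0731), nor with the mean of a gene's probes (0.0891), and the tendon and cartilage median was 0.25. The leukocyte call ended without Cobb EDL replicate 2, Qingyuan soleus replicates 2 or 3 or Qingyuan EDL replicates 1 or 3 (0.0681 to 0.097), and the adipocyte call without Cobb soleus replicate 3, Cobb EDL replicate 2, Qingyuan soleus replicate 2 or Qingyuan EDL replicate 3 (0.0711 to 0.142). The endothelial median was 0.23 without Qingyuan soleus replicate 2. MYH7B was at 10.06 ± 0.94, TNNI1 at 8.84 ± 0.77 and MYL10 at 8.48 ± 1.12 (adjusted p = 0.000222, 0.000135 and 0.00171). TECRL was at 7.72 ± 0.65, TNNI3K at 7.55 ± 0.56 and TNNC1 at 7.49 ± 0.54 (adjusted p = 0.00012, 4.7e-05 and 4.58e-05). PVALB was at −7.23 ± 1.17, MAFA at −4.24 ± 0.61, EMX2 at −3.95 ± 0.54 and GH, the growth hormone gene, at −3.71 ± 0.52 (adjusted p = 0.00387, 0.00237, 0.00186 and 0.00222). GATM was at −3.58 ± 0.86 (adjusted p = 0.0196), a call that ended with slide as a block and without Cobb EDL replicate 3 (0.0527) or Cobb soleus replicate 2 (0.0531). HOXD11, a gene of limb patterning, was called lower in soleus (adjusted p = 0.0127), where it was not above background on any array. With normexp TNNI3K, EMX2 and GH, still called, were at 3.91, −1.64 and −1.24. In all 3954 genes were called, 1744 higher and 2210 lower. A fit with slide as a block called 849, of which 710 were shared, and 11 of the 12 named genes. The count was 2514 and 2054 without Cobb soleus replicates 1 and 2, 2294 and 2218 without Cobb EDL replicates 2 and 3, and 2679 to 4996 without the rest.

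The last comparison asks whether the muscle difference differs between the breeds. FGF23 (chromosome 1, 75455622 to 75455681) was the only gene called, with an interaction of −3.92 ± 0.36 (adjusted p = 0.0085), while 1522 genes had an unadjusted p under 0.05 in limma. Its scaled log2 signal was −2.69 ± 0.415 (SD, n = 3) in Qingyuan EDL, against −6.67 ± 0.235 in Qingyuan soleus, −5.62 ± 0.344 in Cobb EDL and −5.68 ± 0.104 in Cobb soleus. FGF6 (chromosome 1, 75430218 to 75430277), the gene next to FGF23, was at −1.31 ± 0.624 in Qingyuan EDL and at −5.11 ± 0.649, −4.46 ± 0.658 and −5.03 ± 0.0287 in the same other groups. Its interaction was −3.24 ± 0.59 and not called (adjusted p = 0.504). The soleus minus EDL differences of FGF23 and FGF6 in Qingyuan were −3.98 and −3.80 (adjusted p = 4.74e-05 and 0.00115). Each gene had a probe above background on all 12 arrays, which may not be the probe used. Extracellular matrix genes had a median interaction of −0.65 and cell cycle genes of −0.37 (adjusted p = 7.97e-08 and 0.0148, and 0.959 for both with an estimated correlation), with 0 members called in either list. The cell cycle median ran from −0.67 to −0.11 with 1 array left out. With slide as a block neither passed (−0.06 and −0.19, adjusted p = 0.891 and 0.996), while 7 other lists did, among them slow fibre genes (2.20, adjusted p = 1.15e-06; 0.46 and 0.398 without the block). That fit called 4 genes, and FGF23 was not among them (−3.54, adjusted p = 0.115). Interaction values with the block rest on Cobb EDL replicate 1 and Qingyuan soleus replicate 3. With normexp FGF23 was at −1.53 (adjusted p = 0.0379), so its size depends on how dim signal is treated. The FGF23 call also ended with a replicate block (adjusted p = 0.196) and without any Cobb soleus array or Qingyuan soleus replicates 1 or 2 (0.0509 to 0.0613). The interaction count was 91 without Qingyuan soleus replicate 3, 3 without Qingyuan EDL replicate 1, 2 without Cobb EDL replicate 1, 0 without any of the Cobb soleus arrays or Qingyuan soleus replicates 1 or 2, and 1 without the rest.

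**Figure D3:**
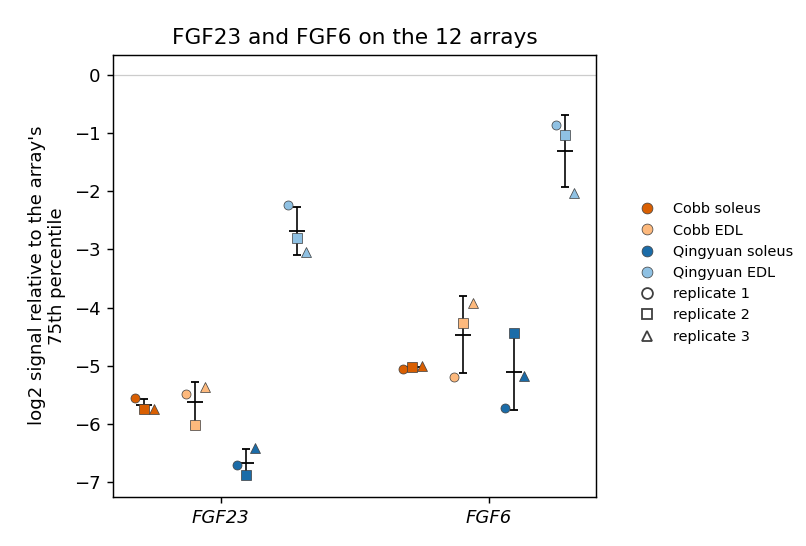
Scaled log2 signal of FGF23 and FGF6 on each array (points) with group means and SD (bars, n = 3). Both lie highest in Qingyuan EDL, at means of −2.69 and −1.31.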

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

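Among the tests in this part, those of genes high in EDL on Cobb EDL replicate 1 and of all splits that part each pair of replicate numbers were chosen only after the result was seen. FGF23 stood out because its muscle difference differed between the breeds in the test of the interaction, at −3.92 (adjusted p = 0.0085). Extracellular matrix genes, with a median interaction of −0.65, and cell cycle genes, with −0.37, stood out in the same way (adjusted p = 7.97e-08 and 0.0148). Both lists had adjusted p = 0.959 with an estimated correlation, and with slide as a block their medians were −0.06 and −0.19 (adjusted p = 0.891 and 0.996). The cell cycle interaction was also no longer past the test without Cobb EDL replicate 1 (0.165), Qingyuan EDL replicate 2 (0.14) or Qingyuan soleus replicates 1 or 2 (0.0887 and 0.301). Adenovirus E1A control spots, which no comparison uses, had a median signal of 53.2 on Qingyuan EDL replicate 1, above all other arrays.

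Cobb EDL replicate 1 lay nearer to soleus than the other two Cobb EDL arrays, at −19.6 on the first principal component against 35.3 and 28.6. Genes high in EDL in the Qingyuan arrays were lower on it by a median log2 difference of −1.76 (45 of 51 genes; quartiles −2.31 and −1.09), where soleus tissue taking the place of EDL tissue allows −0.21 at the upper quartile of its share, which argues against that exchange as the whole cause. Slow-fibre tissue in the sampled piece stays open for the genes high in soleus, whose median apparent share of soleus signal was 0.030 over 111 genes (quartiles 0.00521 and 0.152), with 93 of them (83.8%) raised, between the values set in advance for and against it. A slide effect stays open too, and is hard to separate because this array shares its slide with Cobb soleus. Cobb EDL replicate 1 minus replicate 2 was set against Cobb soleus replicate 3 minus Cobb EDL replicate 3. Over 7508 genes chosen for no muscle difference in Qingyuan these correlated at r = 0.29975 (95% bootstrap interval over genes 0.266 to 0.335). The value set in advance lies inside this interval, and genes are not independent replicates. The second difference is also one of muscle. An array nearer to soleus can thus give a positive r without a slide effect, and the test cannot decide. A different fibre make-up of that muscle was not tested apart from mixed tissue.

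Cell cycle and extracellular matrix genes were lower in Qingyuan in both muscles. Lower overall signal on the Qingyuan arrays is argued against, since 0 of 10000 random lists matched on mean signal had a median as low as any of the 4 list medians (percentile 0), and quantile normalization left the medians at 0.975 to 1.09 times their value. Fewer fibroblasts in the Qingyuan pieces stay open for the matrix part. The 11 identity genes fell less than the 16 matrix genes, with medians of −1.03 against −1.98 in soleus and −0.32 against −1.16 in EDL. The differences were 0.944 and 0.837 (95% bootstrap intervals over genes 0.328 to 1.55 and 0.355 to 1.30). Intervals omit variation between arrays, so whole and partial cause cannot be told apart. Breed and age, which change together, and the make-up of the dividing cells stay open and untested. With slide as a block these lists passed, and with an estimated correlation none did (adjusted p = 0.123 to 0.426).

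A sequence variant under a probe could give a breed difference on that probe alone. Of 719 genes called for breed in the same direction in both muscles, 314 had a second kept probe, and in 260 of them (82.8%) it moved the same way with at least 0.5 of the log2 change. Among genes called for muscle in both breeds this held for 64 of 70 (91.4%), a difference of −8.63 percentage points (95% bootstrap interval −15.9 to −0.373). This argues against such variants as the main cause of the breed calls, while a smaller share of the calls and the genes with 1 probe stay open. Breed or age stays among the untested explanations of these calls.

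Other splits of the samples were fitted in the same way. The 10 splits of 6 arrays are too few for a share under 0.05. In each of these 4 comparisons 1 of the 10 splits, the real one, gave as many genes: 1802 against 1 for the highest other split in breed in soleus, 1438 against 4 in breed in EDL, 290 against 0 in muscle in Cobb and 1635 against 541 in muscle in Qingyuan. Among the 4 splits that part each pair of replicate numbers, the highest other was 0 in both muscle comparisons. For muscle averaged over breeds 1 of 100 splits, the real one, gave as many as 3954 genes, with 59 as the highest other. Because same-numbered samples deviate together, all 32 splits that part each pair were fitted as well, and 1 of these gave as many, with 2 as the highest other. This argues against a chance split of these samples. It does not cover chance between birds, since replicates may not be separate birds, nor the slides, to which muscle is partly tied. For the interaction chance cannot be excluded: 15 of 100 splits called at least the 1 gene of the real split, with 4 as the highest other. Of the 32 splits that part each pair 8 did, 1 of which exchanges the muscles of all Qingyuan samples and so gives the 3954 genes of the averaged contrast.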

How the results depend on the processing

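The comparison within a slide was chosen after seeing the data, and the other alternatives before. Counts moved by more than 1.5 times under several of them, and the cause was not tested. With slide as a block the calls were 331 for breed in soleus, 130 for breed in EDL, 75 for muscle in Cobb, 656 for muscle in Qingyuan, 849 for the averaged muscle contrast and 4 for the interaction, and within a slide again 75 and 656. The block leaves fewer degrees of freedom, and on simulated data without a slide effect it too called fewer changed genes, which excludes nothing about the slides. Its breed values rest on Cobb EDL replicate 1 in soleus and on Qingyuan soleus replicate 3 in EDL, and both share the difference on the second slide. Array weights gave 6267, 2900, 9823 and 7066 for breed in soleus, breed in EDL, muscle in Cobb and the averaged contrast, and 7 for the interaction. Cobb EDL replicates 1 to 3 had weights 0.338, 1.36 and 5.79, so that group rested mostly on replicate 3. Only the 2 groups compared gave 146 for breed in EDL, 568 for muscle in Cobb and 250 for muscle in Qingyuan. Normexp with quantile normalization gave 2373 for breed in EDL, 887 for muscle in Cobb and 3 for the interaction. Muscle in Cobb was also at 623 with quantile normalization, 617 with the values of the deposited table, 164 without the filter and 635 with trend and robust on. A minimum change of 2-fold left 1571 in the averaged contrast. A replicate block gave 0 for the interaction and moved no other count by more than 1.5 times, but the genes differed: it kept 1401 of 1802, 1084 of 1438, 147 of 290, 1157 of 1635 and 3408 of 3954 calls, in the order above, ended 44 of the 196 named gene calls and no gene list call. The share of calls that are higher moved by over 10 points from 39.3% to 57.8% with array weights in breed in soleus, and from 50.6% to 16.9% with slide as a block and 21.2% with only the 2 groups compared in breed in EDL. In muscle in Cobb it moved from 73.1% to 38.6% with array weights, 32.0% with slide as a block, 62.0% with trend and robust on and 59.0% with only the 2 groups compared, and in muscle in Qingyuan from 48.9% to 62.4% with only the 2 groups compared. With arrays left out it ran from 24.2% to 44.9% in breed in soleus, 38.2% to 52.0% in breed in EDL, 43.5% (without Cobb EDL replicate 1) to 97.1% in muscle in Cobb, 39.2% to 62.2% in muscle in Qingyuan and 37.2% to 50.5% averaged over breeds. The interaction has too few calls for such a share.

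Leaving out 1 array at a time gave 576 to 2546 for breed in soleus, 311 to 2431 for breed in EDL, 34 to 1640 for muscle in Cobb, 389 to 2172 for muscle in Qingyuan, 2054 to 4996 for the averaged contrast and 0 to 91 for the interaction. Where this leaves a group with 2 arrays, the spread is pooled over all groups. The breed correlation was 0.547 to 0.658 and the muscle correlation 0.531 to 0.678 in these fits. The breed correlation was 0.665 with normexp and 0.510 with array weights, and the muscle correlation 0.728, 0.567 and, with slide as a block, 0.459. Of 264 named gene results 196 were called, and none of these changed sign under any alternative. Of the 68 not called, 28 changed sign under at least 1, in 104 of 1452 values. Over all 264 and outside the left-out arrays, 2049 values kept their side of the threshold, 44 gained a call and 385 lost it, and with arrays left out these were 2489, 14 and 665.

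Of 58 gene list calls 0 held with an estimated correlation and 25 with fry, and 51 to 58 of them held with 1 array left out. The slide block kept 39 of the 58, lost 16 and turned 3, and the comparison within a slide kept 17 of 23, lost 5 and turned 1. The fast fibre median for breed in soleus, not past the test, turned from 0.18 to −0.29 with normexp and to −0.24 with quantile normalization and with the deposited table, and passed as lower there. With slide as a block the breed in soleus medians of adipocyte, heat shock and endothelial genes were 0.43, 1.20 and 0.46, and the endothelial interaction 0.12. Heat shock and endothelial genes then passed the test, as did that interaction (adjusted p = 0.0482). In all, 18 list tests not past the threshold passed with slide as a block, 4 for breed in soleus, 2 for breed in EDL, 1 for muscle in Cobb, 3 for muscle in Qingyuan, 1 for the averaged contrast and 7 for the interaction. In that fit the extracellular matrix test for muscle in Qingyuan and the cell cycle test for the interaction turned direction while their medians stayed negative, at −0.069 (also within the slide) and −0.19. Single arrays turned heat shock for muscle in Cobb (0.20 without Cobb EDL replicate 1, and from −0.38 without the others), fatty acid oxidation for the interaction (−0.21 without the same array, up to 0.19), cell cycle for muscle in Qingyuan (−0.34 without Qingyuan soleus replicate 3, up to 0.22) and ribosomal protein for the interaction (0.14 without Qingyuan EDL replicate 3, and from −0.070). These 4 passed the test in the turned direction (adjusted p = 0.041, 0.0214, 0.00703 and 0.0464). Signal over background limits the dim genes.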

Other observations

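Of 36 interferon response and antigen presentation genes, 3 were called higher in Qingyuan soleus and 4 in EDL, and the list did not pass the test. Its medians were 0.27 and −0.14 (adjusted p = 0.081 and 0.728), and with slide as a block 0.39 in soleus (adjusted p = 0.0126; adjusted p = 0.636 with an estimated correlation and no block). TAP2, the peptide transporter, rose by 1.53 ± 0.29 in Qingyuan soleus (adjusted p = 0.0126) and B2M, the light chain of MHC class I, by 1.12 ± 0.22 in soleus and 1.13 ± 0.22 in EDL (adjusted p = 0.0153 and 0.0195). IRF9, a transcription factor of the interferon response, rose by 1.25 ± 0.31 and 1.26 ± 0.31 (adjusted p = 0.0355 and 0.0408). With slide as a block none of these was called (TAP2 in soleus at 1.46 and adjusted p = 0.174, B2M at 0.84 and 0.94, adjusted p = 0.4 and 0.36, IRF9 at 2.11 and 1.17, adjusted p = 0.0578 and 0.268). Without Cobb soleus replicates 1 or 2 TAP2 was not called in soleus (0.0521 and 0.0506). B2M lost its call in soleus without Cobb soleus replicates 2 or 3 or Qingyuan soleus replicate 1 (0.0635, 0.0602 and 0.0666) and in EDL without any Cobb EDL array or Qingyuan EDL replicate 3 (0.0501 to 0.0584). The IRF9 calls ended without any of the 3 Cobb soleus or 3 Qingyuan soleus arrays or Cobb EDL replicate 3 in soleus (0.0516 to 0.117). In EDL they ended without any array other than Cobb EDL replicate 1, Qingyuan soleus replicate 3 or Qingyuan EDL replicate 1 (0.0517 to 0.127). A replicate block ended both IRF9 calls (0.0632 and 0.0667), and quantile normalization and dropping the filter that in EDL (0.0538 and 0.0563).

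Of 29 adipocyte and lipid storage genes 3 were called lower in Qingyuan EDL and 0 higher, and the list did not pass the test there (median −0.14, adjusted p = 0.21). FASN, the fatty acid synthase, was at −1.11 ± 0.25 in soleus and −1.18 ± 0.25 in EDL (adjusted p = 0.0258 in both), and FADS1 and FADS2 were at −1.24 ± 0.26 and −1.62 ± 0.31 in EDL (adjusted p = 0.0237 and 0.0168). CXCR4, a chemokine receptor, was at −3.12 ± 0.36 in soleus (adjusted p = 0.00177; −3.45 and adjusted p = 0.0659 with slide as a block) and −1.48 ± 0.36 in EDL (adjusted p = 0.0417; −1.49 and adjusted p = 0.402 with slide as a block). Its call in EDL ended without any of the 6 Cobb arrays or Qingyuan EDL replicates 2 or 3 (0.0528 to 0.116), with normexp (−0.30, 0.136), without the filter (0.0571) and with a replicate block (0.0679). With slide as a block FADS1 in EDL stayed called (−2.15, adjusted p = 0.0329) and FADS2 did not (adjusted p = 0.196), and FASN was called in neither muscle (−0.44 and −1.08, adjusted p = 0.671 and 0.272). FASN lost its call in soleus without any of the 3 Cobb soleus arrays or Qingyuan soleus replicates 1 or 2 (adjusted p = 0.0528 to 0.105), and in EDL without Cobb EDL replicates 1 or 3 or Qingyuan EDL replicate 3 (0.0587, 0.0722 and 0.0788). With the mean of a gene's probes FASN was called in neither muscle (adjusted p = 0.136 and 0.101). FADS2 lost its call in EDL without Cobb EDL replicates 2 or 3 (0.0541 and 0.0519), and FADS1 without these or Qingyuan EDL replicates 2 or 3 (0.0705, 0.0876, 0.0564 and 0.0566).

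FGF23 and FGF6 are neighbours and both were high in Qingyuan EDL. A hypothesis is that their stretch of chromosome 1 changes as a block. Of the 5 nearest genes on each side, 2 of 10 were measured, CCND2 and NDUFA9, and 0% of these were called with the same sign in breed in EDL and muscle in Qingyuan. CCND2 was at −0.09 in breed in EDL and NDUFA9 at 0.19 (adjusted p = 0.828 and 0.628). With so few measured neighbours, a change of the stretch and one of these genes alone cannot be told apart.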
